A study of Mus musculus with 6 samples.

How the data were processed

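Total RNA of whole mouse skin, taken 5 days after birth, was measured on 6 single-sample Affymetrix expression arrays. Per the labels, 3 samples came from FVB mice and 3 from GC13 mice, a transgenic line that overexpresses Hoxc13. The deposited values were intensities on a linear scale, 1 for each of 12488 probe sets on each array, and all were above 0. The software behind these intensities, its background correction and any detection calls are not given in the sources used here. From the values, each array had been scaled by 1 factor so that the mean of its intensities, with the highest and lowest 2% left out, was 100.

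The 66 control probe sets were left out of the comparison and used only for the 3' over 5' ratios of Gapdh and beta-actin. The other 12422 probe sets were set on the log2(intensity + 2) scale, where 2 was the 10th percentile of all intensities rounded to a whole number. A fold change on this scale is smaller than one from the intensities themselves for dim probe sets, whose signal over background is unknown. The medians of the log2 values differed by up to 0.345 between arrays, above the limit of 0.2 set in advance, so each array was centred on its median. The 25% of probe sets with the lowest mean over the 6 arrays were left out, whatever their change, which left 9316.

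Gene names came from the platform annotation supplied with the series, updated through Entrez identifiers with the RefSeq gene table of assembly GRCm38.p6, which was used only for names, chromosomes and neighbourhood. Of the 12422 probe sets, 10833 had 1 gene symbol, 396 listed several genes and stayed unnamed, and 1193 had no gene listed. The Entrez identifier of 10817 of the named probe sets was found in the RefSeq table. The sources used here name no genome build for the array, so no coordinates are given. A gene measured by several probe sets stood by the one with the highest mean over the 6 arrays, which gave 6867 genes, 1287 of them with more than 1 tested probe set. Where other probe sets of a named gene disagreed, this is stated.

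GC13 was compared with FVB by limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over the 9316 probe sets and a threshold of 0.05. Every log2 fold change is GC13 minus FVB, with its standard error (SE) from that fit. A further 24 gene lists were fixed in advance, covering the hair follicle, epidermis, dermis, other cell types of skin, RNA quality and sex. The 23 lists with at least 4 measured members were tested with camera at a preset inter-gene correlation of 0.01, which asks whether a list moved relative to the other genes, with Benjamini-Hochberg adjustment over the lists. Each list was tested again with an estimated correlation and with fry, which asks whether the list's genes move one way on balance and compares them with no other genes. The limma p-values of a list's members were also adjusted over that list alone by Benjamini-Hochberg. This corrects neither over the other lists nor over the other probe sets, and it was not among the tests fixed in advance. Members that pass only there are not calls at the stated threshold. The 3' over 5' ratios were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1.

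The genes named in the text followed a rule fixed in advance. Hoxc13 and Foxq1 were named in any case. Among genes past the threshold whose 3 intensities in a group all lay above those of the other group, the rule took up to 14 with the largest change in each direction. Where fewer than 10 passed, those with the smallest unadjusted p filled up to 10 and are stated as not past the threshold. From each list it took the 4 members with the smallest p, from which the examples were drawn. Igfbp3, Col6a2, Rptn, Krt2, Krt71, Krt25, Krt27, Strada, Vasp, Ddx49, Derl2, Ykt6 and the genes of the closing section that lie outside the rule were named after their values were seen.

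The scripts were tested on simulated arrays with the mean of each real probe set and 1 spread per probe set from the fit, equal in both groups. With 200 of 9316 probe sets changed by 1 on the log2 scale in the comparison of GC13 with FVB, the fit recovered 0.575% of them. With a change of 2, it recovered 97.3% of them and 5.51% of its calls were false. A list of genes shifted by 0.5 was called in 100% of the simulations and other lists in 0% of them. The simulated genes varied independently of each other, while the estimated correlation in the real keratin-associated protein list was 0.38. These rates therefore do not give the share of false calls among the real lists. No simulated array was deviant, while GC13 replicate 2 lay apart from its group in the real data. The rates for single probe sets may thus not carry over to the real calls. In these simulations a change of 2-fold was rarely detected in single probe sets.

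The alternatives fixed before the data were examined were other pseudocounts, filters and scalings, a variance trend, array weights, a test without moderation, the replicate number as a block, the mean of a gene's probe sets, other set tests, and leaving out each array. A pseudocount of 32, and the combinations that leave out GC13 replicate 2 together with that pseudocount or with an estimated correlation, were added after the data had been seen.

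Several tests of the closing section were also changed after their values had been seen. The count of lower probe sets with GC13 replicate 2 lowest was first set against probe sets low in GC13 replicates 1 and 3, a choice that by its selection works against replicate 2 being lowest, then against random probe sets of like mean intensity, and last against those of like GC13 mean, since that replicate reads lowest near the floor. By the comparator tried at the start, replicate 2 was lowest for 77 of 444 probe sets (17.3%), against 61.1% of the called ones. None of these comparators was chosen as the called probe sets were, so the count decides nothing for loss of RNA. What the tests of RNA loss, of the dimmer probe sets of the same genes, of sex and of interferon-induced genes would have to show was reworded after their values were known. An explanation of the calls without GC13 replicate 2 by background in dim probe sets was computed and dropped, and only its counts are given.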

Results

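The series compared whole skin of mice that overexpress Hoxc13 with whole skin of FVB mice, an albino inbred strain. Hoxc13 encodes a homeodomain transcription factor of the hair follicle that controls hair keratin genes. The 3 GC13 samples came from the transgenic line and the 3 FVB samples from FVB mice, all at 5 days after birth, when the hair coat is growing. Whole skin holds epidermis, hair follicles, dermis, fat and underlying muscle, so a transcript level reflects both the cells present and their expression. The deposited intensities summed to between 1626361 and 1736141 per array, with medians from 29.0 to 37.4. The number of arrays, 3 per group, limited the precision. The labels do not say whether the samples of a group came from separate mice, so p-values measure the spread between these samples, which may be technical. The annotation used here gave Hoxc13 no probe set, so the level of the overexpressed gene, which would have checked the labels, was not analysed here.

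The RNA of the GC13 samples differed from that of the FVB samples in the balance of transcript ends. The 3' over 5' intensity ratio of the Gapdh control probe sets, which rises where the 5' part of messenger RNA is lost, was 0.931, 0.958 and 0.894 on the FVB arrays and 2.22, 9.58 and 2.19 on the GC13 arrays. Its log2 value was -0.11 ± 0.05 (SD, n = 3) in FVB and 1.85 ± 1.22 (SD, n = 3) in GC13, and the exact permutation test gave p = 0.1, the smallest it allows. The beta-actin ratio was 3.80 on GC13 replicate 2 and between 1.16 and 1.43 on the other arrays, and the exact permutation test between the groups gave p = 0.2. GC13 replicate 2 also lay apart from its group on principal component 1, which held 45.7% of the variance, at -34.0 against 27.6 and 45.4 for replicates 1 and 3. The FVB arrays lay at -17.8, -17.8 and -3.35, on the side of GC13 replicate 2. Component 2, with 31.2% of the variance, parted the groups, with FVB between 18.4 and 22.4 and GC13 between -41.8 and -8.50. The Y-linked gene Eif2s3y had intensities of 69.4, 98.9 and 79.6 in FVB and of 3.25, 143 and 4.60 in GC13. Uty, also on the Y chromosome, had 13.3, 15.2 and 13.8 in FVB and 4.87, 34.7 and 7.19 in GC13. Xist, the RNA that coats the inactive X chromosome, was dim on all arrays, with 9.95, 11.9 and 11.7 in FVB and 9.15, 1.07 and 12.6 in GC13.

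**Figure D1:**
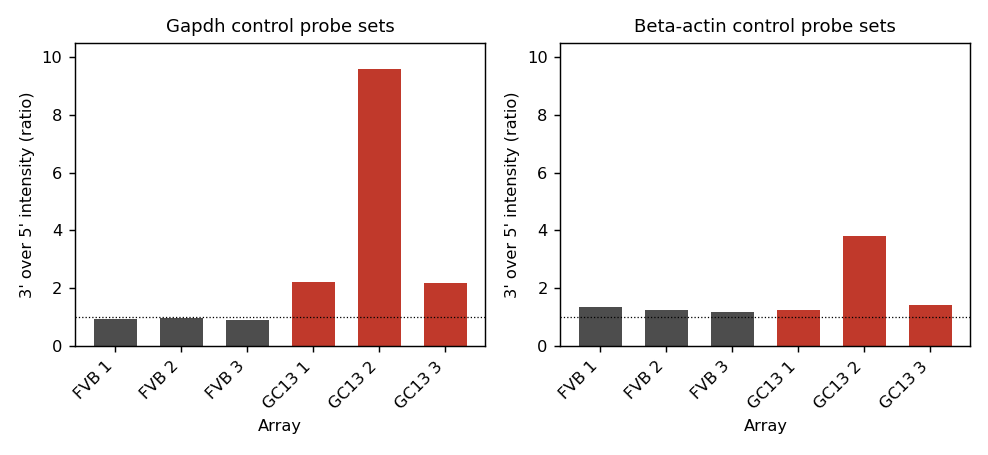
Ratio of 3' to 5' intensity of the Gapdh and beta-actin control probe sets on each array, 1 bar per array, with FVB in grey, GC13 in red and a dotted line at a ratio of 1. The Gapdh ratios of the FVB arrays lie below 1 and those of the GC13 arrays at 2.19, 2.22 and 9.58.

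The comparison of GC13 with FVB asks how added Hoxc13 alters gene expression in skin. The Gapdh ratio was higher on every GC13 array than on every FVB array, so RNA quality cannot be told apart from the line. This holds for the rises and the list shifts below as well as for the falls. Folds below come from the fit on the centred scale, and intensities are the deposited ones. Krt72, a keratin of the inner root sheath of the hair follicle, fell 2.58-fold, from an intensity of 1136 ± 69.8 (SD, n = 3) to 420 ± 57.1 (SD, n = 3). Krt77, an epidermal type II keratin, fell 2.48-fold, from 1093 ± 51.5 to 418 ± 39.9. Vcan, which encodes the matrix proteoglycan versican, rose 2.49-fold, from 156 ± 17.4 to 370 ± 5.90, and Penk, which encodes the opioid precursor proenkephalin, rose 2.40-fold, from 304 ± 12.8 to 704 ± 121. As groups, the inner root sheath, keratin-associated protein, hair shaft regulator and melanocyte lists fell, and the dermal matrix, cell cycle, skeletal muscle and endothelial lists rose in the camera test. No list was past the threshold with an estimated correlation, where the smallest adjusted p was 0.319 and 2 lists, melanocyte and dermal matrix, had an unadjusted p under 0.05.

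Genes of the inner root sheath and companion layer, which mould the growing hair, were lower in GC13 as a group. Of 11 measured members 1 fell, Krt72, and 10 did not pass the test, while 2 fell when adjusted over the list alone, Krt72 and Padi1. Krt72 (Entrez 105866) had a log2 fold change of -1.37 (SE 0.19, limma adjusted p = 0.0351), and Padi1, a peptidylarginine deiminase gene, had -0.97 (SE 0.20, limma adjusted p = 0.0894 over all probe sets). Padi3 and the transglutaminase gene Tgm3 had log2 fold changes of -0.55 and -0.76, neither past the threshold. The keratin genes Krt71, Krt25 and Krt27, all brighter than Krt72, had 0.35, 0.05 and -0.03, so the fall was not shared by every keratin of the list. Of the 11 members 9 lay below 0 and 2 above. The list's median was -0.55 (camera adjusted p = 0.005; adjusted p = 0.319 with an estimated correlation). On GC13 replicate 2, the array with the Gapdh ratio of 9.58, the same list had a median of -0.01 relative to the FVB mean, and without that array the camera adjusted p was 0.0154.

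None of the 39 measured hair shaft and matrix regulators passed over all probe sets, and 7 fell and 1 rose when adjusted over the list alone. Foxn1, whose loss causes the nude phenotype, had 47.0 ± 6.12 (SD, n = 3) in FVB and 8.24 ± 9.48 (SD, n = 3) in GC13, a log2 fold change of -2.60 (SE 0.55, limma adjusted p = 0.1). That fold change ran from -3.32 to -0.96 over the alternatives. Foxq1, mutated in satin mice with abnormal hair, had 122 ± 11.4 in FVB and 58.2 ± 7.55 in GC13, a log2 fold change of -0.97 (SE 0.24, limma adjusted p = 0.135). Without GC13 replicate 2 its limma adjusted p was 0.0108, in a fit where 1379 of 9316 probe sets passed. Foxq1 missed the threshold under 15 of 17 alternatives. Dlx3, a homeobox gene of the hair matrix, had 703 ± 34.6 and 371 ± 28.0, and Wnt5a had 33.1 ± 2.04 and 13.1 ± 2.54, with log2 fold changes of -0.85 and -1.16. The 1 that rose in the list alone was Igfbp3, with a log2 fold change of 0.92. The list's median was -0.11, with 18 members above 0 and 21 below (camera adjusted p = 0.00982; adjusted p = 0.319 with an estimated correlation). Without GC13 replicate 2, which had a median of -0.01 for this list, the camera call was lost at an adjusted p of 0.0738.

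Structural genes of the hair shaft had no member past the threshold over all probe sets. Among the 10 measured hair keratins 1, Krt84, fell when adjusted over the list alone, with 81.9 ± 4.15 in FVB and 40.8 ± 7.66 in GC13. A dimmer probe set of Krt84 had a log2 fold change of -3.18 against -0.91 for the brighter one, and neither passed. The highly expressed Krt83 and Krt86 had 2348 ± 104 and 2215 ± 126 in FVB and 1431 ± 307 and 1591 ± 530 in GC13. The hair keratin list had a median of -0.28 and was not past the threshold (camera adjusted p = 0.0512), though it passed under 8 of 17 alternatives. The keratin-associated proteins, which cross-link hair keratins, fell as a list with a median of -0.32 (camera adjusted p = 0.0389; adjusted p = 0.552 with an estimated correlation), with none of 11 members past the threshold, also when adjusted over the list alone. Krtap5-4 had 842 ± 20.7 in FVB and 446 ± 299 in GC13, and Krtap12-1 had 294 ± 5.33 and 159 ± 113. On GC13 replicate 2 the list's median was 0.18 relative to the FVB mean, and without that array the list had a median of -0.54 and a camera adjusted p of 0.00486. The 21 measured Hox genes had no member past the threshold, and the largest difference was that of Hoxa7, with 34.5 ± 9.88 and 9.05 ± 4.42 (limma adjusted p = 0.126). Their median of 0.08 and mean of -0.05 differed in sign, and the camera adjusted p was 0.602 with the direction down.

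**Figure D2:**
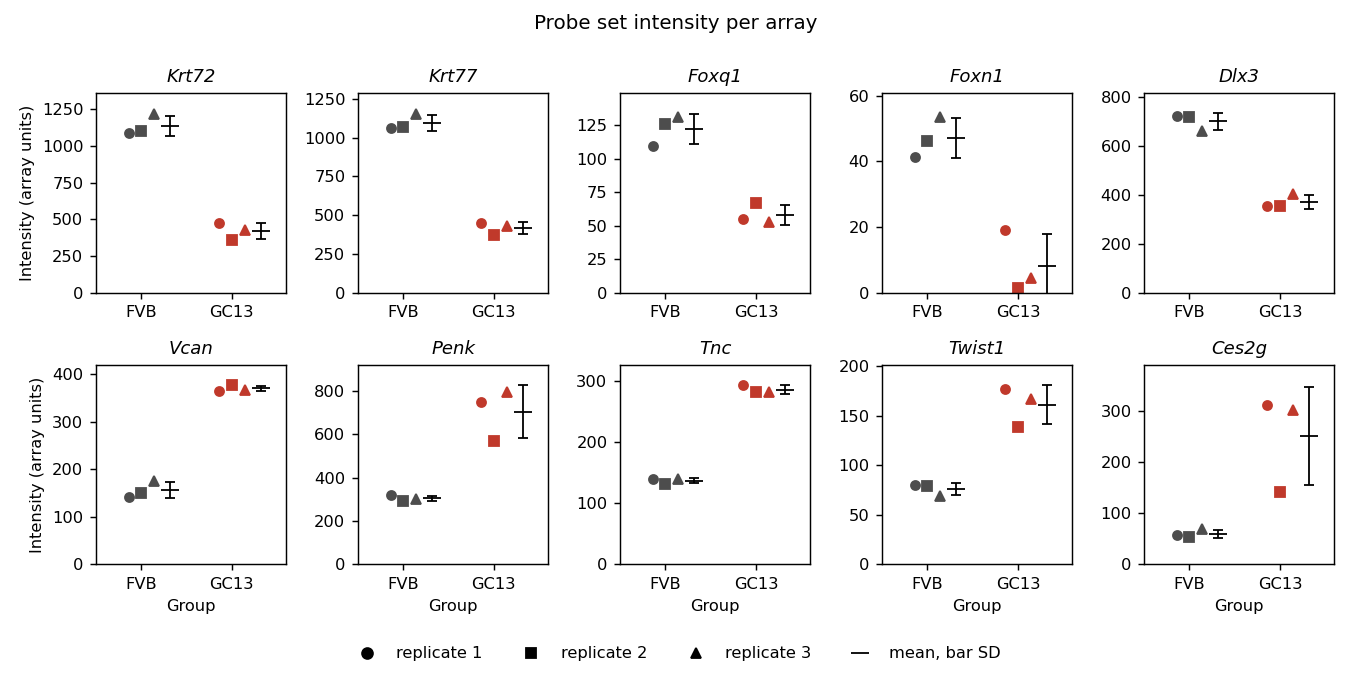
Deposited intensity on a linear axis for 10 genes in FVB (grey) and GC13 (red), 1 point per array with the replicate number as its shape, and the mean with a bar of 1 SD beside the points (the bar of Foxn1 in GC13 ends at the axis). Krt72 and Krt77 lie between 361 and 474 on the GC13 arrays and at 1060 or above on the FVB arrays, while Vcan lies at 366 to 377 against 142 to 175.

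In the epidermis, genes of terminal differentiation went both ways. Of 19 measured cornified envelope and granular layer genes 1 fell, Krt77 (log2 fold change -1.31, SE 0.19, limma adjusted p = 0.037), and 18 did not pass. Adjusted over the list alone 4 rose (Flg, Alox12b, Krt1 and Rptn) and 2 fell (Krt77 and Krt2). Flg, which encodes filaggrin, had 750 ± 37.1 (SD, n = 3) in FVB and 1513 ± 390 (SD, n = 3) in GC13, and Krt1, a keratin of differentiating keratinocytes, had 1289 ± 126 and 2829 ± 1172. Krt2 was measured by 2 probe sets, of which the dimmer passed at -1.95 (SE 0.24) and the brighter did not, at -0.63 (SE 0.20). The list had a median of 0.31 and was not past the threshold (camera adjusted p = 0.311). Among 20 stress-induced epidermal genes Sprr2b rose 3.49-fold (limma adjusted p = 0.042) and Sprr2f fell 3.71-fold (limma adjusted p = 0.0342). Both belong to a family of near-identical small proline-rich proteins, so their probe sets can take up signal from other members, and 2 further probe sets that list several Sprr2 genes passed at 1.88 and 1.69. Adjusted over the list alone 3 rose (Sprr2b, Serpinb3a and Sprr2d) and 1 fell (Sprr2f), and the list's median was 0.26 (camera adjusted p = 0.122). The 12 basal keratinocyte genes had a median of 0.14 (camera adjusted p = 0.804). The 15 desmosome and adherens junction genes had a median of 0.08 and a mean of -0.09, with the camera direction down (adjusted p = 0.725), and neither list had a member past the threshold over all probe sets or over the list alone.

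Dermal matrix genes rose as a group. Of 29 measured members 1 rose, Vcan (Entrez 13003; log2 fold change 1.32, SE 0.21, limma adjusted p = 0.0489), and 28 did not pass, while 5 rose when adjusted over the list alone (Vcan, Col5a1, Col6a3, Eln and Col6a2). Col5a1 had 364 ± 13.6 (SD, n = 3) in FVB and 763 ± 189 (SD, n = 3) in GC13, and Col6a3, a collagen VI chain, had 939 ± 36.5 and 1914 ± 467. Eln, which encodes elastin, had 868 ± 13.0 and 1731 ± 474. Further probe sets of Col5a1 and Eln, both dimmer, had log2 fold changes of 0.01 and -0.96. The list's median was 0.45, with 24 members above 0 (camera adjusted p = 0.000161; adjusted p = 0.319 with an estimated correlation). On GC13 replicate 2 the median was 0.57, and without that array the camera adjusted p was 0.00403. Tnc and Twist1, a matrix glycoprotein gene and a mesenchymal transcription factor gene outside the list, had log2 fold changes of 1.13 (SE 0.20, limma adjusted p = 0.0669) and 1.14 (SE 0.20, limma adjusted p = 0.0643).

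Melanocyte genes fell as a group, with 9 of 10 members below 0 and none past the threshold over all probe sets. Oca2, a melanosome transporter gene, had 70.9 ± 1.33 (SD, n = 3) in FVB and 32.9 ± 4.67 (SD, n = 3) in GC13 and was the 1 member that fell when adjusted over the list alone. Pmel and Tyrp1 had log2 fold changes of -0.83 and -0.58. The list's median was -0.47 (camera adjusted p = 0.0011; adjusted p = 0.319 with an estimated correlation) and -0.49 on GC13 replicate 2. Cell cycle genes rose as a list of 35 with a median of 0.34 (camera adjusted p = 0.00982; adjusted p = 0.357 with an estimated correlation), and none passed over all probe sets or over the list alone. Among them Pola1, the catalytic subunit gene of DNA polymerase alpha, had 67.9 ± 7.34 and 118 ± 26.1, and Mcm4, a replicative helicase gene, had 206 ± 3.06 and 296 ± 7.75. Endothelial genes rose as a list of 16 with a median of 0.42 (camera adjusted p = 0.0389; adjusted p = 0.319 with an estimated correlation), again with none past either threshold. Eng had 199 ± 11.3 and 412 ± 189, while Cldn5 had 134 ± 6.47 and 82.1 ± 19.4. Skeletal muscle genes rose as a list of 33 with a median of 0.27 (camera adjusted p = 0.0177; adjusted p = 0.319 with an estimated correlation). None passed over all probe sets and 3 rose when adjusted over the list alone (Myh3, Casq1 and Ldb3), of which Casq1 had 217 ± 9.79 and 403 ± 84.6. On GC13 replicate 2 the medians were 0.49 for cell cycle, 0.40 for endothelial and 0.15 for skeletal muscle genes. At the preset correlation, the camera call was lost under 7 of 17 alternatives for endothelial and under 3 for skeletal muscle genes. By fry, whose adjusted p was 0.00265 for melanocyte, 0.02 for dermal matrix and 0.0164 for both endothelial and stress-induced genes, 4 lists passed.

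The other lists did not pass in camera and had no member past the threshold over all probe sets. The 28 macrophage, T cell and antigen presentation genes had a median of 0.12 (camera adjusted p = 0.804), and the complement gene C1qa, which fell when adjusted over the list alone, had 71.9 ± 10.2 in FVB and 19.4 ± 11.9 in GC13. Mast cell genes had a median of 0.53 over 6 members (adjusted p = 0.108), where Cma1 had 500 ± 14.9 and 803 ± 184. Sebaceous gland and lipid synthesis genes had a median of -0.11 over 27 members (adjusted p = 0.101), and 3 fell when adjusted over the list alone, Nsdhl, Dgat1 and Hsd17b7. Of the other probe sets of Nsdhl 1 was lower (-0.94) and 1 higher (0.35), and that of Dgat1 was higher (0.86). The 12 Schwann cell and nerve genes had a median of 0.12 (adjusted p = 0.435), and Ncam1 rose when adjusted over the list alone, with 91.2 ± 3.33 and 172 ± 53.2. Adipocyte genes had a median of 0.12 over 22 members (adjusted p = 0.743) and erythroid genes -0.15 over 11 (adjusted p = 0.725). Immediate early and heat shock genes had a median of 0.13 over 24 members with the camera direction down (adjusted p = 0.804). Ribosomal protein genes had a median of 0.12 over 25 members (adjusted p = 0.435) and mitochondrial respiratory chain genes 0.07 over 63 (adjusted p = 0.743), and both medians turned negative with quantile normalization, at -0.12 and -0.05. The 3 sex-linked genes were too few to test as a list, and none passed with all 6 arrays. Without GC13 replicate 2, the Y-linked Eif2s3y passed at -3.85 (limma adjusted p = 0.00139) and Uty at -1.04 (limma adjusted p = 0.0163). In that comparison a difference in sex cannot be told apart from that of the line. With all 6 arrays, GC13 replicates 1 and 3 still had far lower Eif2s3y than every FVB array. The groups may therefore be unbalanced for sex in the main comparison too, which was not adjusted for.

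**Figure D3:**
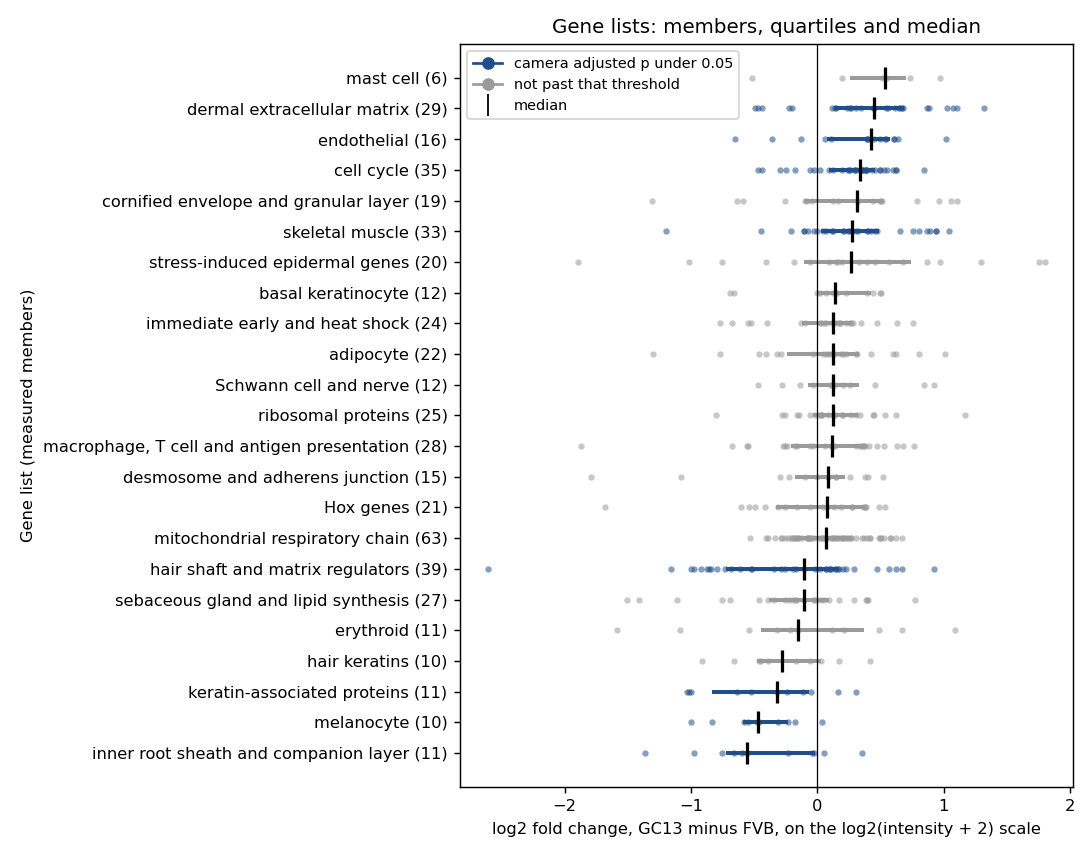
Log2 fold change of GC13 minus FVB for the measured members of 23 gene lists, 1 point per gene, with a line over the middle quartiles and a black mark at the median, in blue where the camera adjusted p was under 0.05. The medians run from -0.55 for the inner root sheath list to 0.53 for the mast cell list, which was not past the threshold.

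Outside these lists, single genes with known roles elsewhere were among the calls. Ces2g, a carboxylesterase gene, rose 4.10-fold, from 59.5 ± 7.61 (SD, n = 3) to 251 ± 95.7 (SD, n = 3), with intensities of 311, 141 and 302 on the GC13 arrays. Polr2a, the gene of the largest subunit of RNA polymerase II, rose 2.74-fold, from 144 ± 15.4 to 382 ± 70.5, while its second probe set had a log2 fold change of 0.74. The chemokine receptor gene Cxcr3 rose from a dim 3.58 ± 0.49 to 13.9 ± 3.33, and its log2 fold change ran from 0.40 to 1.76 over the alternatives, lowest with a pseudocount of 32. Plagl1, an imprinted zinc finger gene, and Zbed3 had log2 fold changes of 1.26 (SE 0.20, limma adjusted p = 0.0522) and 1.28 (SE 0.23, limma adjusted p = 0.0683). The largest falls were those of H2-D4, a histocompatibility gene of a family with near-identical members, from 68.8 ± 9.38 to 5.32 ± 3.48, and of the ubiquitin protease gene Usp22, from 40.5 ± 5.49 to 2.54 ± 1.59. Both were dim in GC13, and over the alternatives their log2 fold changes ran from -3.581 to -1.395 and from -3.585 to -1.029. Cd82, a tetraspanin gene, fell 3.83-fold from 297 ± 23.9 to 75.4 ± 28.1, and its second, dimmer probe set had a log2 fold change of 0.35. Sgip1, Qsox1, Zfp276, Six5, Fut2, Trabd, Dnase1l2, Sephs2, Asb6 and Plekho1 also fell, with limma adjusted p from 0.0164 to 0.0489, as did Strada, Vasp, Ddx49, Derl2 and Ykt6. Of the 21 genes that fell, 17 lay among the dimmer 50% of the tested probe sets and 9 had a GC13 mean under 10.

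Over all tested probe sets, 44 passed the limma threshold with Benjamini-Hochberg adjustment, 8 higher and 36 lower in GC13, and 27 of 6867 genes passed, 6 higher and 21 lower. With the deposited scaling in place of centring, 28 probe sets passed, 2 higher and 26 lower, and 16 genes, 0 higher and 16 lower, so Vcan, Penk, Ces2g, Sprr2b, Polr2a and Cxcr3 all missed the limma threshold there. At an unadjusted p under 0.05 there were 1440 probe sets with the opposite balance, 794 higher and 646 lower, and 24.5% of the tested probe sets had no overlap between the groups, where chance gives 10%. Without GC13 replicate 2, 1379 probe sets passed, 559 higher and 820 lower, with all 44 among them. Without FVB replicate 1, 2 or 3 limma gave 0 probe sets, with 768, 803 and 946 at an unadjusted p under 0.05, and without GC13 replicate 1 or 3 it gave 9 and 11, all of them lower in GC13. The counts therefore rest on which arrays enter the fit. The log2 fold changes of Krt72, Krt77, Vcan and Penk kept their sign under every alternative tried. Their values did not overlap between the groups, so leaving out an array could not turn the sign. Their calls were lost under 6, 7, 10 and 11 of 17 alternatives.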

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

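The tests of RNA loss, of other probe sets, of sample identity, of sex and of the H2 genes were chosen only after the results they concern had been seen, and the count of other splits was planned. The Gapdh control probe sets, which no comparison of genes used, had 3' over 5' ratios of 2.22, 9.58 and 2.19 on GC13 replicates 1, 2 and 3, above the FVB range of 0.894 to 0.958. The beta-actin control probe sets had a ratio of 3.80 on GC13 replicate 2, above the FVB range of 1.16 to 1.36.

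The 36 probe sets that were lower in GC13 may partly reflect lost 5' RNA and not lower transcript levels. Of 16 further probe sets of 13 of these genes, as bright as the called one or brighter, 2 were lower at an unadjusted p under 0.05, and among them those of Iqgap1, Mknk2 and Mapre1 lay between 0.02 and 0.33, which argues against a fall of the whole transcript for these genes. For the 23 probe sets with no such partner, 1 of 2 dimmer probe sets was lower, too few to decide on a change of the whole transcript. Over all 20 further probe sets, bright or dim, 5 were lower at that p. Among these were dimmer probe sets of Spin1 at -0.71 and of Sirpa at -1.36. GC13 replicate 2, with the highest Gapdh ratio, was the lowest GC13 array for 22 of the 36, against 15.6 for random probe sets of like mean intensity (upper-tail permutation p = 0.0225 over 100000 draws) and 14.9 for those of like GC13 mean (permutation p = 0.0108), but the 36 were called with that array in the fit, which can make a deviant array the lowest, so loss of 5' RNA stays open. The Gapdh ratio was raised on every GC13 array but the beta-actin ratio of GC13 replicate 1, 1.26, lay within the FVB range, and added Hoxc13 stays open as an untested cause for the single genes, and the positions of the probes were not used here.

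Leaving out GC13 replicate 2 raised the calls from 44 to 1379, in a pattern that splits the GC13 samples. For the 820 probe sets that were lower in replicates 1 and 3, replicate 2 lay 1.06 above them at the median and on their side of FVB for 47.6%, and for the 559 higher ones it lay 0.30 above FVB and on their side for 73.5%; choosing them by replicates 1 and 3 alone can bring the 1.06 about, so loss of 5' RNA stays open. Whether replicate 2 is a GC13 sample cannot be told apart from a noisier one. Of 50 bright probe sets called without it, it lay nearer to GC13 for 20 (40%, exact interval 26.4% to 54.8%), 11 of 16 higher and 9 of 34 lower ones. Choosing these 50 by replicates 1 and 3 alone can lower that count. Replicate 2 correlated at 0.943, 0.940 and 0.929 with the FVB arrays and at 0.922 and 0.896 with GC13 replicates 1 and 3. On principal component 2, however, it lay on the GC13 side. Sex could contribute, since replicates 1 and 3 had low Eif2s3y and replicate 2 did not. Without replicate 2, 14.2% of X-linked genes were called against 14.3% of autosomal ones. A difference in sex need not raise the X-linked share, so this leaves any effect of sex open. The effect of Hoxc13 itself remains an untested explanation.

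H2-D4 was the 1 of 30 H2 probe sets with 1 gene listed that passed the threshold, 1 further probe set that lists several H2 genes passed at -3.06, and the H2 genes as a group were not shown to change more often than other genes (6 of 23 at an unadjusted p under 0.05, 26.1% against 14.4%, two-sided Fisher exact p = 0.131). Of the 30 probe sets 6 were lower and 1 higher at that p, among them H2-Q4 at -1.70 and 1 of the 3 probe sets of H2-D1 at -1.06, its other 2 at -0.44 and -0.51. Genes lying between the H2 genes, by the order in the GRCm38.p6 table, reached that p in 17.5% of cases against 14.4% for other genes (one-sided Fisher exact p = 0.121), so another haplotype in the GC13 line stays open. Both Fisher tests counted changes in either direction. Lower at that p were 5 of the 23 H2 genes, 23 of 223 genes between them and 410 of 6621 other genes. Whether this is an excess of lower genes was not tested. Interferon-induced genes outside the complex had a median of 0.0223 over 12 genes that went both ways, with Isg15 at -0.77 and Ifit2 at 0.77, which leaves a lower interferon response open. An effect of Hoxc13 was not tested.

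Of the 10 splits of the 6 arrays into 3 and 3, 1 split, the real one, gave as many as 44 probe sets, 1 as many as 27 genes and 1 as many as 8 gene lists. The highest of the other splits gave 0 probe sets, 0 genes and 2 lists, and 10 splits are too few for a share under 0.05.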

How the results depend on the processing

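The pseudocount of 32, alone or without GC13 replicate 2, and the estimated correlation without that replicate were tried only after the data had been seen. With 44 probe sets, 27 genes and 8 lists past the threshold as the starting point, leaving out 1 array gave 0 to 1379 probe sets, 0 to 981 genes and 5 to 9 lists. The extremes were each FVB array (0) and GC13 replicate 2 (1379), and without GC13 replicate 3 there were 5 lists. With the lowest 50% of probe sets left out there were 23 probe sets, 17 genes and 4 lists, with fewer genes tested. A pseudocount of 6 gave 41 genes, and one of 32 gave 119 probe sets and 85 genes, or 2281 and 1704 without GC13 replicate 2. The deposited scaling gave 28 probe sets and 16 genes, array weights 3850 (2050 higher, 1800 lower) and 2813, the test without moderation 1 and 1, and the mean of a gene's probe sets 17 genes. By fry 4 lists passed, and 0 by camera with an estimated correlation, with or without GC13 replicate 2 (smallest adjusted p 0.319 and 0.661, with 2 and 0 lists at an unadjusted p under 0.05). The cause of these moves was not tested, apart from fewer samples or genes where a setting removes them.

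With the replicate block there were 78 probe sets, 16 higher and 62 lower, and 42 genes. Deviations from the group means correlated at -0.07, 0.18 and 0.36 for replicates 1, 2 and 3, and 2 of the 3 numbers matched best with their own. With 3 arrays per group, this check cannot tell whether the numbers are a pairing. The number of lists stayed at 8.

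Directions by camera turned for these lists, given as medians, with the lowest and highest when 1 array is left out: Hox genes with the lowest 50% left out (0.10), array weights (0.21) or without GC13 replicate 2 (-0.0543 to 0.16), macrophage and T cell genes with the lowest 50% left out (0.11) or without GC13 replicate 2 (0.0173 to 0.22), immediate early genes with the lowest 50% left out (0.13), the mean of probe sets (0.14) or without GC13 replicate 3 (-0.0529 to 0.25), ribosomal proteins with quantile normalization (-0.12), mitochondrial genes with quantile normalization (-0.0451) or without GC13 replicate 2 (0.00513 to 0.19), basal keratinocyte genes without FVB replicate 3 or GC13 replicate 1 (0.0584 to 0.29), and desmosome genes with the mean of probe sets (0.23). Uty turned positive without GC13 replicate 1 or 3 (-1.04 to 0.28 over the arrays left out) and with a pseudocount of 32 (0.030). The cause was not tested. None of these was past the threshold to begin with.

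Among named genes, 1613 of the comparisons under alternatives kept direction and side of the threshold, 156 lost the call, 169 gained one and 3 turned. Among lists these counts were 346, 18, 12 and 14. Most of the named genes and lists were not past the threshold to begin with, and only those past it can lose a call. The counts kept therefore do not show how stable the calls are. The inner root sheath, melanocyte, cell cycle and dermal matrix lists kept their camera call at the preset correlation under each of 17 alternatives, and none kept it with an estimated correlation. At the preset one the highest adjusted p was 0.027, 0.0175, 0.0466 and 0.00403, and skeletal muscle lost it under 3, hair shaft regulators under 3, keratin-associated proteins under 5 and endothelial genes under 7. Hair keratins gained it under 8, with adjusted p from 0.000994 to 0.227, and the sebaceous gland and mast cell lists under 2 each. Krt72 lost its call under 6, Krt77 under 7, Vcan under 10 and Penk under 11, with limma adjusted p up to 0.301, 0.301, 0.341 and 0.301. Planned values for Hoxc13 could not be given, as no probe set was named for it, and the test without moderation gives no set test. Without detection calls, signal over background is unknown for dim probe sets, which limits the calls among them.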

Other observations

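The genes of this part were chosen after their values were seen. Hbb-b2, an adult beta-globin gene, and 2 keratin-associated protein genes had like values on GC13 replicate 2 and the FVB arrays and far lower ones on GC13 replicates 1 and 3. Hbb-b2 had 629, 682 and 640 in FVB, 127 and 109 on GC13 replicates 1 and 3, and 610 on replicate 2. Krtap5-4 had 859, 849 and 819 in FVB, 256 and 292 on GC13 replicates 1 and 3, and 790.3 on replicate 2. Krtap12-1 had 299, 294 and 289 in FVB, 97.4 and 90.8 on GC13 replicates 1 and 3, and 289.8 on replicate 2. The desmosomal cadherin gene Dsc2 lay between, with 136 on replicate 2, 37.0 and 40.7 on replicates 1 and 3, and 239, 239 and 190 in FVB. Of the calls made without replicate 2, 135 of 559 higher and 199 of 820 lower probe sets lay in the brightest 25% of tested probe sets, and 192 and 148 in the dimmest 25%.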
